A study of Gallus gallus with 36 samples.

How the data were processed

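DNA methylation was measured by reduced representation bisulfite sequencing (Zymo-Seq RRBS, per the labels' protocols) in 36 samples of chicken breast tissue, 6 from each of 6 locations. The deposited files give, for each sample and each cytosine position, the coverage as a read count and the methylation level as a fraction of the reads, and neither was found to be normalized from its values. Per the submitters' processing notes, bcl2fastq 2.20.0.422, Trimmomatic 0.38 and BSMAP 2.9 were used with the genome build galGal5; the notes used here give neither the role nor the order of these tools. How reads were trimmed at fragment ends, whether duplicates were removed and which positions were filtered are not given in the sources used here. Trimming bears on the levels, because cytosines added to fragment ends during library preparation report the added nucleotides and not the sample.

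The coverage and fraction files of a sample held the same positions in the same order, and coverage multiplied by fraction was a whole number of reads, within a tolerance of 0.02 reads, for 100% of positions in every sample. Methylated reads were taken as this product. Between 3 and 37 positions per sample, whose coordinates were written in exponent form, were left out. The remaining positions of all samples formed a set of 4662607 positions, 4011528 of them on numbered autosomes. Start coordinates were read as counting from 0, as in the BED format, and windows are given counting from 1.

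Total coverage ranged from 18593636 reads summed over positions (Australia 2) to 332285153 (Germany 6), and median coverage per listed position ranged from 4 to 35 reads. The reads carry no molecular identifiers, so intervals based on read counts would cover counting error only. The spread between samples was used for each test instead.

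The mean methylation level of a sample was the mean over the 478394 autosomal positions with at least 10 reads in all 36 samples, each position weighted equally. Locations were compared by a permutation test of the one-way F statistic (100000 permutations, two-sided by construction) and, for the 15 pairs of locations, by two-sided exact permutation tests over the 924 splits of 12 samples, with Benjamini-Hochberg adjustment over the pairs. With no gene annotation of the build used here, the same F test was run for chromosomes 1 to 5, chromosomes 6 to 12 and the remaining numbered chromosomes.

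For regional tests, reads were summed over windows of 500 bp. A position counted in a sample with at least 10 reads and coverage no higher than the sample's 99.9th percentile. A window needed 3 such positions in a sample and at least 5 samples in every location, which left 36882 windows with a median of 30.0 positions and 1084 reads per sample. A quasi-binomial logistic model with location as the only factor was fitted to the methylated and unmethylated reads of each window over all samples. A location's level in this model was that of its summed reads, so deeper samples weighed more. The location means and SDs given in the text weigh each sample equally. Dispersions were moderated across windows with limma's squeezeVar. The 6 locations were compared by an F test, and each location was compared with the mean of the other 5 on the logit scale, with Benjamini-Hochberg adjustment over windows. A window was called at an adjusted p under 0.05 together with a difference of at least 10 percentage points, between the highest and lowest location mean or between a location and the mean of the other 5 location means. Similarity of samples was tested by PERMANOVA on Euclidean distances over the 27010 windows measured in all samples, and by the number of samples whose nearest other sample came from the same location (100000 permutations each).

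Windows named in the text followed a rule. For the test of all locations, these were the 20 called windows with the largest difference, at most 1 per 10 kb. For each location they were the 3 windows with the largest difference in each direction among called windows in which all measured samples of the location lay on the same side of the median of the other samples. Windows named outside this rule are said to have been chosen after their values were seen. The tests, thresholds, naming rule and gene lists were fixed before the data were examined. Promoter tests, gene list tests and cell type marker tests were not run, because no gene annotation of galGal5 was used here. A table of chicken genes on another assembly was not used, and no window was assigned to a gene.

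The window test was tested on simulated data: beta-binomial reads were drawn for the 36882 windows at their real coverage, level and dispersion, and 200 windows with a mean level of 35 to 65% were changed in 1 location each. Of windows changed by 10 percentage points 63.3% were called, and of those changed by 20 or 30 percentage points 98.6% were called. Among 36682 unchanged windows 10.5% had an unadjusted p under 0.05, so the unadjusted p-values were too small. Of these unchanged windows 76 had an adjusted p under 0.05, and 7 were also past the 10 percentage point minimum. These counts do not estimate false calls in the real data, where 16606 windows had an adjusted p under 0.05. The adjustment is less strict where more windows pass. Reads of a window were also drawn at a level that did not depend on position, so differences from the positions measured could not arise.

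Most positions came in adjacent pairs, the cytosines of the opposite strands of a CpG site, and many pairs had opposite levels. After this was seen, an alternative set was added that kept only pairs whose positions differed by at most 20 percentage points in the pooled reads of all samples, called concordant pairs. It held 2990460 autosomal positions, of which 392089 had at least 10 reads in all samples, and 33341 windows. Because a position counted in a sample only with at least 10 reads, the reads of a window were summed over different positions in different samples, and more so where coverage was low. After this was seen, windows were tested again over shared positions, which were those that counted in every sample measured in the window. At least 3 were required, which left 31525 windows, and 28887 windows over the shared positions of concordant pairs. The shared positions were also tested with 10 reads drawn from each, so that a position had the same weight in every sample. The values of these sets are given beside the main ones. Genotype-like positions, 1975 in number, were those where at least 90% of samples lay at 0 to 15%, 35 to 65% or 85 to 100%, with at least 3 samples at 0 to 15% and at least 3 above 35%.

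The alternatives were a minimum of 5 or 20 reads, no upper limit on coverage, windows of 200 or 1000 bp, windows measured in all 36 samples, all chromosomes and unplaced sequences, no minimum difference or one of 20 percentage points, and reads thinned to 10 per position. They also included genotype-like positions left out, covariates for depth, chromosome W coverage and replicate number, limma on logit levels, other weightings of the mean level, a rank-based distance, and each sample left out in turn. Replicate pairs within a location differed by more than read-counting noise (mean chi-square per window 1.94 to 8.07), so no samples were merged as 1 library. Separate libraries from the same bird would differ by more than counting noise too, so this does not show whether the samples came from separate birds, and each sample was counted on its own. Python 3.11.15 with NumPy 2.4.6, SciPy 1.17.1 and pandas 2.3.3, and R 4.3.3 with limma 3.58.1 were used.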

Results

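DNA methylation was profiled in breast tissue of chickens (Gallus gallus) from Australia, Finland, Germany, Iran, Thailand and the USA, with 6 samples per location and 36 in all. In reduced representation bisulfite sequencing, DNA is cut at CCGG sites and short, CpG-rich fragments are sequenced after bisulfite conversion, so that the share of unconverted reads at a cytosine gives its methylation level. The design asks how methylation differs between locations. The labels name no control location, breed, age or sex, so flock, keeping, handling and processing cannot be separated from location. Nothing in the labels says that the samples of a location came from separate birds, so p-values measure only the spread between these samples, which may be technical. Chromosome Z coverage relative to the numbered chromosomes was 0.559 in USA 1 and 0.541 in USA 5, against 0.905 to 1.22 in 33 others. This argues against a single bird as the source of the USA samples.

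Sequencing depth differed between samples and locations. The median coverage of a sample's positions averaged 19.7 ± 5.82 reads in Finland (SD, n = 6), 19 ± 7.10 in Thailand, 13 ± 11.3 in Germany, 12 ± 5.18 in the USA, 11 ± 3.03 in Iran and 8.83 ± 2.64 in Australia. Coverage summed over positions ranged from 18593636 reads in Australia 2 to 332285153 reads in Germany 6. Each sample listed between 2379353 and 3904373 positions. Of 818625 CpG pairs with at least 360 pooled reads at both positions, 112921 (13.8%) had positions more than 50 percentage points apart. The median pooled level in these discordant pairs was 97.1% at the high position and 5.02% at the low position. The high positions held 6.37% of reads in Thailand, 6.53% in Australia, 6.74% in Iran, 6.82% in the USA, 7.11% in Finland and 7.13% in Germany. Values over concordant pairs, which leave these positions out, therefore stand beside the main values. Samples were also measured at different positions of a window, and the median number of positions per tested window was 22 in Australia, 25 in Germany, 27 in Iran, 29 in the USA, 37 in Finland and 39 in Thailand. Values over shared positions, those read in all samples measured in the window, are given as well; both sets were chosen after the data were seen.

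Australian samples had the highest mean methylation level and Iranian samples the lowest. The mean level over 478394 shared positions was 17.5% ± 0.258 in Australia (SD, n = 6), 17.1% ± 0.109 in Finland, 17.0% ± 0.119 in Germany, 16.9% ± 0.219 in Thailand, 16.9% ± 0.396 in the USA and 16.6% ± 0.347 in Iran. The locations differed by more than the spread between samples (F = 8.15, permutation p = 9.0e-05). Of the 15 pairs of locations, 6 differed at an adjusted p under 0.05: Australia exceeded each of the other 5 locations, by 0.389 percentage points over Finland to 0.922 over Iran, and Finland exceeded Iran by 0.533 (adjusted exact p = 0.0271 for each). Weighting each read equally put Iran above Australia, with a difference of -0.313 percentage points. Averaging each sample over all of its own positions left a difference of 0.0494 in favour of Australia.

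Over concordant pairs the Australian level stood further apart. The mean level over 392089 positions was 9.22% ± 0.285 in Australia (SD, n = 6), against 8.33% ± 0.0959 in Finland, 8.32% ± 0.232 in Thailand, 8.31% ± 0.134 in Germany, 8.13% ± 0.368 in the USA and 7.94% ± 0.355 in Iran (F = 16.5, permutation p = 1.0e-05, the smallest the permutations give). Australia differed from each other location, with an adjusted exact p of 0.0130 against the USA and 0.00812 against the others, and no other pair passed. Over 329389 concordant positions with a pooled level under 10%, Australia averaged 2.14% ± 0.201 and the other locations between 1.08% ± 0.135 (Iran) and 1.36% ± 0.0757 (Thailand), with a permutation p of 1.0e-05. These positions made up most of the 392089, and incomplete conversion, weighed below, stays open as a part of the difference there. Over 54608 concordant positions at 10 to 80%, Australia averaged 40.01% ± 1.02 and the others between 37.3% ± 1.70 (Iran) and 39.1% ± 0.540 (Germany), with a permutation p of 0.0228. Over 8092 concordant positions above 80%, the location means ranged from 88.7% ± 0.653 (USA) to 89.6% ± 0.432 (Australia), a difference that did not pass the test (permutation p = 0.0845).

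**Figure D1:**
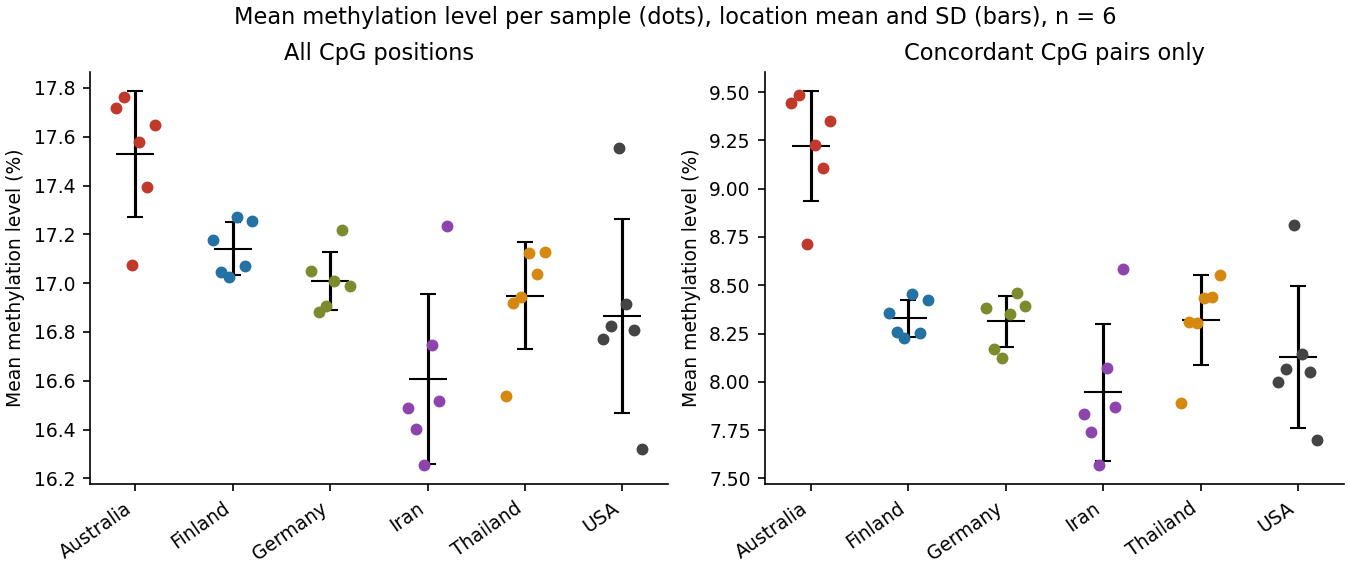
Mean methylation level (%) of each sample by location, over all shared CpG positions and over concordant CpG pairs; dots are samples, the horizontal bars location means and the error bars SDs (n = 6). The vertical axes do not start at 0, and Australian samples lie between 17.1% and 17.8% over all positions and between 8.71% and 9.49% over concordant pairs.

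Over all positions methylation was higher on the small chromosomes in every location, and the order of Australia and Iran held in each chromosome class. Levels by class over concordant pairs are not given here, so discordant pairs stay open as a part of the rise toward small chromosomes. On chromosomes 1 to 5 the mean level was 14.99% ± 0.185 in Australia and 14.2% ± 0.253 in Iran (SD, n = 6 each). On chromosomes 6 to 12 it was 17.5% ± 0.259 and 16.6% ± 0.345, and on the remaining numbered chromosomes 21.2% ± 0.388 and 20.1% ± 0.491. The locations differed in all 3 classes, with adjusted permutation p-values of 3.0e-05, 0.000195 and 0.00106. Weighting each read equally reversed the order of Australia and Iran in each class as well.

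Samples resembled others from their own location in some locations and not in others. The nearest sample came from the same location for all 6 Australian and all 6 Finnish samples, for 5 of 6 Iranian and 5 of 6 Thai samples, for 2 of 6 German samples and for none of the USA samples. The nearest sample was Finnish for 4 German and 4 USA samples and Iranian for the other 2 USA samples. In total 24 of 36 samples had their nearest sample at the same location, where 5.14 would be so by chance (permutation p = 1.0e-05). Location took up 28.9% of the variation between samples over 27010 windows (permutation p = 1.0e-05, the smallest the permutations give in both tests). Over concordant pairs these values were 23 samples and 28.5%, and over shared positions 20 samples and 25.5%, with 5 Australian, 6 Finnish, 5 Thai, 3 Iranian, 1 German and no USA sample. Random groups of the same sizes would take up a part of the variation too, so not all of each share belongs to location. The Finnish samples, which were nearest to most of the German and USA samples, also had the highest mean of median coverage (19.7 ± 5.82 reads, SD, n = 6).

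**Figure D2:**
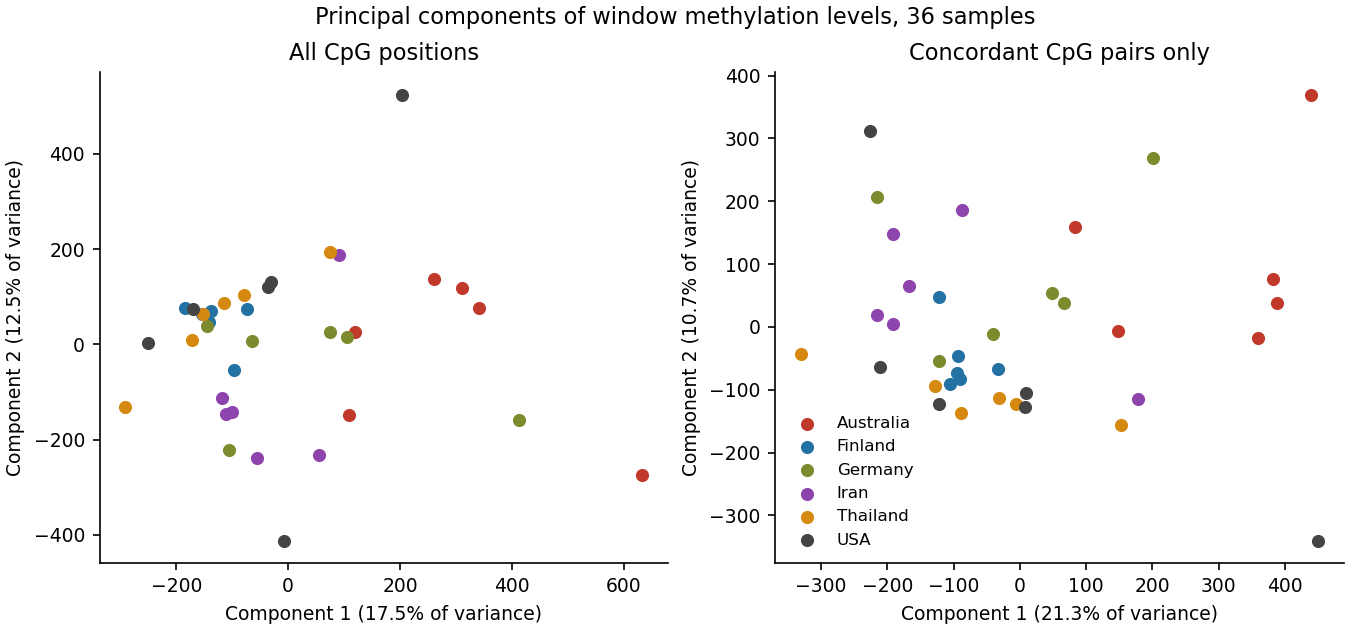
First and second principal components of window methylation levels, for all CpG positions and for concordant CpG pairs, with 1 point per sample coloured by location. The axes give the share of variance, 17.5% and 12.5% over all positions and 21.3% and 10.7% over concordant pairs.

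Windows of intermediate methylation held most of the differences between locations. Of 36882 windows 1580 (4.28%) were called, and windows with a mean level of 20 to 80% made up 37.2% of those tested and 90.8% of those called (odds ratio 18.4, Fisher's exact test); the 10 percentage point minimum makes calls near 0 or 100% harder. Over shared positions 785 of 31525 windows (2.49%) were called, and 92.0% of these had a level of 20 to 80%. Of the 1580 windows 1049 could be tested over shared positions, 376 (35.8%) were called again, and the median window kept 63.8% of its difference. The share of windows called was higher on the remaining numbered chromosomes than on chromosomes 1 to 5, with 5.51% against 3.17% over all positions and 3.15% against 1.91% over shared positions, and neighbouring windows are not independent. On chromosome 27, 79 of 1050 windows were called over all positions (odds ratio 1.86, adjusted Fisher's exact p = 4.2e-05) and 42 of 855 over shared positions (odds ratio 2.08, adjusted p = 0.00144). Mean levels were higher on the small chromosomes, and no comparison at like levels was made. Level can therefore account for a part of these contrasts between chromosomes. Without the minimum difference 16606 windows had an adjusted p under 0.05 over all positions and 12564 over shared positions.

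Australia had the highest mean in 573 of the 1580 called windows and the lowest in 477, and over shared positions the highest in 328 of 785 and the lowest in 203. Over concordant pairs 1466 of 33341 windows were called, and Australia had the highest mean in 908 of them and the lowest in 160. Of the 1580 windows 1072 could be tested over concordant pairs and 739 (68.9%) were called again, and over the shared positions of concordant pairs 327 of 746 (43.8%). Called windows were mostly scattered: 1022 of 1246 stretches over all positions and 586 of 673 over shared positions, in which neighbours lay at most 10 kb apart, held a single called window. With shared positions thinned to 10 reads each, which leaves fewer reads for the test, 159 windows were called.

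Of the 20 windows with the largest differences 15 could be tested over shared positions, and 6 were called again. The values of these follow over shared positions (SD, n = 6 unless given). The adjusted p-values of the 20 windows come from the F test of all 6 locations, and the pair of locations named was not tested on its own. On chromosome 1 at 120148001 to 120148500 (galGal5, as are all coordinates here) the level over 3 positions was 86.0% ± 8.94 in Finland and 55.4% ± 21.5 in Germany (n = 5; adjusted p = 0.00226). On chromosome 9 at 14944501 to 14945000 it was 70.1% ± 7.97 in Australia (n = 5) and 40.3% ± 10.6 in Finland over 4 positions (adjusted p = 0.00470), and over concordant pairs the difference was 36.7 percentage points (adjusted p = 0.00112). On chromosome 24 at 5662001 to 5662500 Germany lay at 68.4% ± 4.79 and the other locations between 76.6% and 82.1% over 4 positions (adjusted p = 3.1e-07). On chromosome 3 at 10491001 to 10491500 the level over 3 positions was 70.2% ± 9.39 in Germany (n = 5) and 52.1% ± 6.47 in Iran (adjusted p = 0.000121). On chromosome 27 at 615501 to 616000 it was 40.6% ± 5.68 in Finland and 26.0% ± 2.41 in Iran over 7 positions (adjusted p = 1.2e-06), but the difference was 2.26 percentage points over concordant pairs. With the shared positions thinned to 10 reads the difference was 29.5 percentage points on chromosome 9 (adjusted p = 0.0484), the one call of these 6 to hold with these fewer reads. It was 24.9 between Finland and Germany on chromosome 1 (adjusted p = 0.296), 9.58 between Australia and Germany on chromosome 24 (adjusted p = 0.203) and 11.4 between Germany and Iran on chromosome 3 (adjusted p = 0.104), against 30.6, 11.2 and 18.1 before thinning. At 615501 on chromosome 27 it was 0 (adjusted p = 0.864).

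The largest difference over all positions, also among these 6, lay on chromosome 27 at 483001 to 483500, with 56.1% ± 28.1 in Thailand and 4.87% ± 1.54 in Finland (SD, n = 6 each; adjusted p = 3.3e-06). All 24 samples at 11.5% or lower were measured at 4 positions and all 12 samples at 45.6% or higher at 14 or 17 positions. Over the 4 shared positions Thailand lay at 20.1% ± 22.02, the USA at 21.6% ± 15.7 and Finland at 4.87% ± 1.54 (n = 6 each; adjusted p = 0.0392). With these thinned to 10 reads the difference between Thailand and Finland was 17.9 percentage points (adjusted p = 0.0669), against 15.3 before. In the other windows among the 20 with the largest differences, the difference shrank or reversed over shared positions, or could not be tested there. Between Australia and Iran it reversed to -4.44 percentage points on chromosome 14 at 692001 (adjusted p = 0.244). Between Australia and Thailand it reversed to -1.58 on chromosome 24 at 1481501 (adjusted p = 0.0966). It reversed to -1.38 on chromosome 5 at 36389001 (adjusted p = 0.0575) and to -4.48 on chromosome 8 at 28851501 (adjusted p = 4.2e-06). These adjusted p-values too belong to the F test of all locations, so none of them tests the reversed difference itself. On chromosome 25 at 2867001 to 2867500 the level was 79.4% ± 5.02 in Australia and 53.4% ± 12.6 in the USA over all positions (n = 6 each; adjusted p = 3.4e-05), and 79.0% ± 3.65 and 74.4% ± 2.58 over 7 shared positions (adjusted p = 0.310). On chromosome 5 at 17525501 to 17526000 Australia exceeded Thailand by 28.5 percentage points over all positions, by 27.8 with each position thinned to 10 reads (adjusted p = 0.0643) and by 7.09 over 3 shared positions (adjusted p = 0.0724). On chromosome 13 at 3461501 to 3462000, with 86.6% ± 7.99 in Australia and 52.5% ± 9.22 in Thailand (n = 6 each; adjusted p = 9.7e-05), the Australian samples were measured at 4 to 6 positions and the Thai ones at 10 to 25, and 2 shared positions were too few for a test. Over these 2 the level was 91.1% ± 9.66 in Australia and 63.6% ± 27.4 in Thailand, a difference of 27.6 percentage points against 34.1 over all positions.

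**Figure D3:**
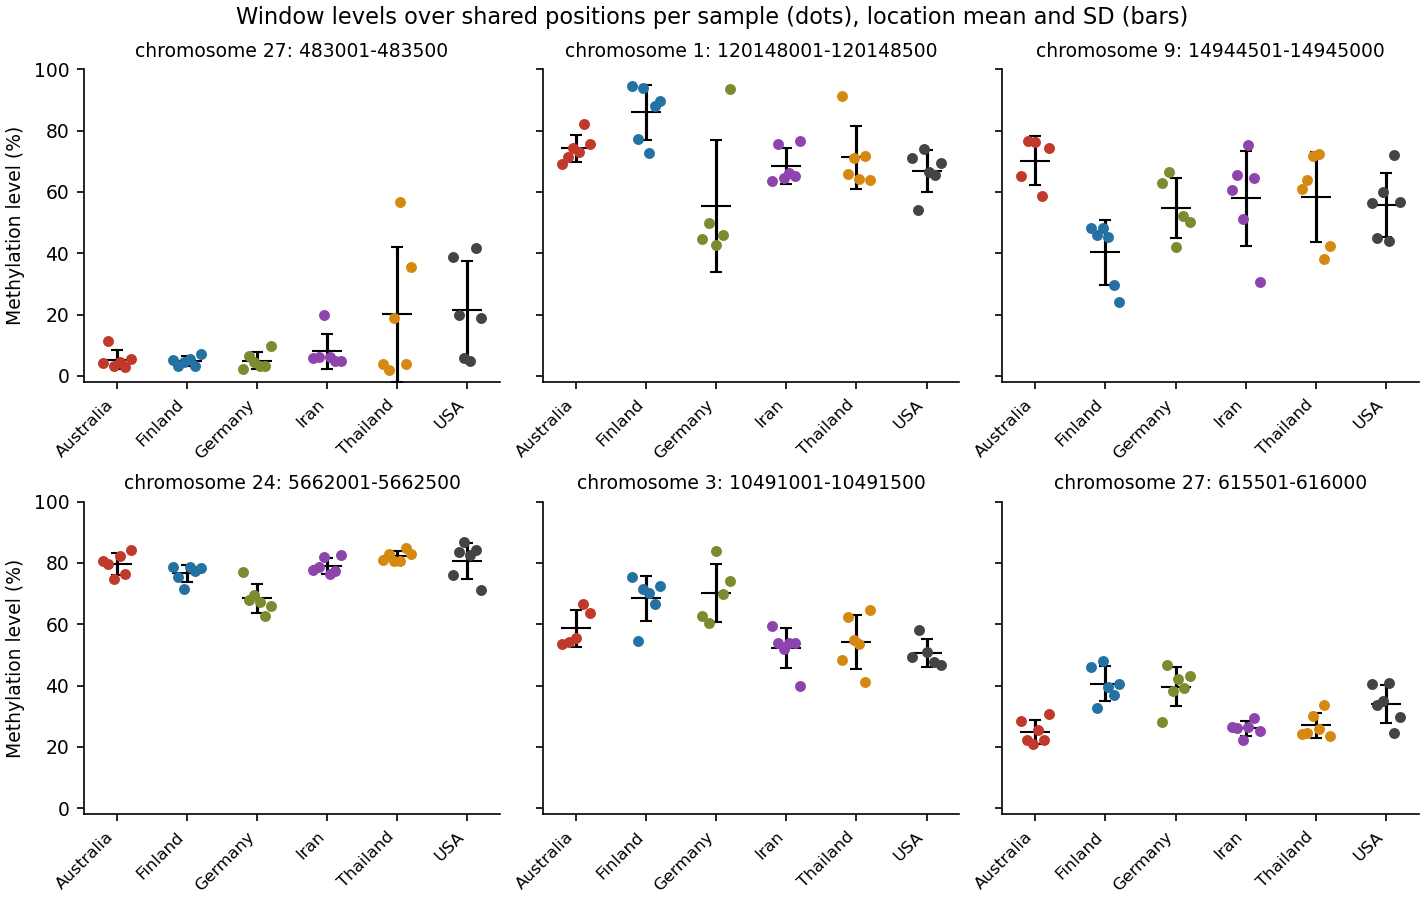
Methylation level (%) by location over shared positions in the 6 windows that were among the 20 largest differences over all positions and were called again over shared positions; dots are samples, the horizontal bars location means and the error bars SDs (n = 5 or 6). The widest difference between location means in these panels, 30.6 percentage points, is on chromosome 1 between Finland and Germany.

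Australian samples differed from the rest by at least 10 percentage points in more windows than samples of any other location. In 277 windows Australia was called against the mean of the other locations, higher in 184 and lower in 93, over concordant pairs in 435, higher in 397 and lower in 38, and over shared positions in 182, higher in 136 and lower in 46. On chromosome 15 at 7568001 to 7568500, a window chosen after its values were seen, Australia lay at 69.0% ± 2.28 (SD, n = 6) and the other locations at a mean of 47.5% over 38 shared positions (adjusted p = 2.6e-07), and with these thinned to 10 reads each the difference was 21.6 percentage points (adjusted p = 2.0e-05). Of 175 windows that could be tested over shared positions 40 were called again, 31 higher and 9 lower, and the median window kept 52.3% of its difference. In each window that the naming rule gave for a single location, all measured samples of that location lay on the same side of the median of the other samples. Of the 6 named Australian windows 2 could be tested over shared positions and neither was called, and none had enough concordant pairs for a test. On chromosome 2 at 103633501 to 103634000 Australia lay at 67.2% ± 2.31 (n = 6) and the other locations at a mean of 41.9% (adjusted p = 0.000491), but over the 6 positions at which each Australian sample was measured the difference was 4.84 percentage points (adjusted p = 0.0285). On chromosome 3 at 65049501 to 65050000 Australia lay at 43.5% ± 10.4 (n = 5) against 19.7% (adjusted p = 0.000368), with 18.3 percentage points after thinning each position to 10 reads (adjusted p = 0.0757) and -0.517 over 3 shared positions (adjusted p = 0.815). The remaining 4 shared at most 2 positions, among them chromosome 11 at 6468001 to 6468500, with 20.3% ± 7.44 (n = 5) against 41.0% (adjusted p = 0.000296). With 10 reads per position the difference there was -10.9 percentage points (adjusted p = 0.149), against -20.8 before thinning. Without the minimum difference Finland had more windows than Australia over all positions, 11046 against 10139, and fewer over shared positions, 5592 against 12127. The direction then turned between the sets, with 2011 Australian windows higher and 8128 lower over all positions, 3301 and 8826 over shared positions, and 12112 and 956 over concordant pairs.

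Thai samples were called in 82 windows, higher in 8 and lower in 74, over concordant pairs in 82, higher in 24 and lower in 58, and over shared positions in 21, higher in 6 and lower in 15. Of 53 windows that could be tested over shared positions 5 were called again, 3 higher and 2 lower, and the median window kept 19.6% of its difference. On chromosome 13 at 1784001 to 1784500, where all measured samples were read at the same 3 positions, Thailand lay at 53.4% ± 5.47 (SD, n = 6) and the other locations at a mean of 38.6% (adjusted p = 0.00698), but with 10 reads per position the difference was 0.667 percentage points (adjusted p = 0.882). On chromosome 5 at 21494001 to 21494500 Thailand lay at 60.5% ± 7.85 (n = 6) against 48.0% (adjusted p = 0.00235), and over concordant pairs the difference was 15.05 percentage points (adjusted p = 0.00236). In the 3 named windows with lower Thai levels the positions measured differed. On chromosome 5 at 36389001 to 36389500 Thailand lay at 40.7% ± 3.70 (n = 6) against 57.7% (adjusted p = 0.0145), with -3.33 percentage points over 3 shared positions (adjusted p = 0.680). On chromosome 26 at 563501 to 564000 it lay at 15.4% ± 6.52 (n = 6) against 32.4% (adjusted p = 0.00674), with 22 to 70 positions in the Thai samples, 3 in each Australian one and 1 shared, at which the difference was -0.150 percentage points. On chromosome 13 at 3461501 to 3462000 it lay at 52.5% ± 9.22 (n = 6) against 69.5% (adjusted p = 0.0162), and over the 2 shared positions the difference was -19.5 percentage points, against -16.99 over all positions, with no test. With limma on logit levels the adjusted p-values were 0.0529 on chromosome 5 at 21494001, 0.0813 on chromosome 5 at 36389001, 0.0681 on chromosome 26 and 0.118 on chromosome 13 at 3461501. Without the minimum difference 841 windows were higher and 2260 lower over all positions, against 2357 and 1198 over concordant pairs and 1011 and 233 over shared positions. Thinning each position to 10 reads moved the count to 357 over all positions, with 46 higher and 311 lower.

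Finnish samples were called in 32 windows, higher in 17 and lower in 15, over concordant pairs in 28, higher in 7 and lower in 21, and over shared positions in 27, higher in 17 and lower in 10. Of 19 windows that could be tested over shared positions 7 were called again, 6 higher and 1 lower, and the median window kept 65.9% of its difference. On chromosome 9 at 14944501 to 14945000 Finland lay at 35.9% ± 10.3 (SD, n = 6) and the other locations at a mean of 56.2% (adjusted p = 0.000370). The difference there was -25.5 percentage points over concordant pairs (adjusted p = 0.00247) and -19.1 over 4 shared positions (adjusted p = 0.00155), but with these thinned to 10 reads the Finnish call did not hold, at -16.35 (adjusted p = 0.177). On chromosome 1 at 120148001 to 120148500 Finland lay at 76.9% ± 6.54 (n = 6) against 60.2% (adjusted p = 0.000667), with 18.7 percentage points over 3 shared positions (adjusted p = 0.00116) and 14.4 with these thinned (adjusted p = 0.507). In the named window on chromosome 2 at 103633501 the Finnish difference was -12.8 percentage points over all positions and -1.76 over shared positions (adjusted p = 0.305). With limma on logit levels its adjusted p was 0.152. On chromosome 27 the level at 615501 to 616000, 38.3% ± 8.75 (n = 6) against 16.9%, was higher by 10.3 percentage points over shared positions (adjusted p = 0.000248) and by 1.04 over concordant pairs (adjusted p = 0.608). At 626501 to 627000 it was 31.5% ± 4.21 (n = 6) against 15.4%, with 0.376 percentage points over concordant pairs (adjusted p = 0.363) and no shared position. Thinning each position to 10 reads ended both of these calls on chromosome 27, with differences of 6.67 percentage points (adjusted p = 0.195) and 2.38 (adjusted p = 0.477). With no upper limit on coverage the first was 0.492 (adjusted p = 0.345), and with limma on logit levels the second had an adjusted p of 0.0869. Without the minimum difference 10056 windows were higher and 990 lower over all positions, against 1170 and 553 over concordant pairs and 4977 and 615 over shared positions. Over concordant pairs leaving out Finland 6 moved the count to 18, with 1 higher and 17 lower.

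German samples were called in 33 windows, higher in 26 and lower in 7, over concordant pairs in 32, higher in 18 and lower in 14, and over shared positions in 16, higher in 9 and lower in 7. Of 13 windows that could be tested over shared positions 7 were called again, and the median window kept 94.5% of its difference. On chromosome 3 at 10491001 to 10491500 Germany lay at 64.5% ± 9.67 (SD, n = 5) and the other locations at a mean of 45.8% (adjusted p = 0.0164), with 13.4 percentage points over 3 shared positions (adjusted p = 0.006996). With log10 mean coverage as a covariate this call was lost (adjusted p = 0.0606). On chromosome 5 at 55927501 to 55928000 it lay at 47.7% ± 19.6 (n = 5) against 65.8% (adjusted p = 0.000425), with -17.2 percentage points over 3 shared positions (adjusted p = 0.00104). On chromosome 17 at 9106501 to 9107000 it lay at 67.7% ± 8.44 (n = 5) against 49.3% (adjusted p = 0.00472), and the difference was 18.5 percentage points over concordant pairs (adjusted p = 0.00507) and 20.9 over 2 shared positions, too few for a test. Thinning each position to 10 reads raised the adjusted p above 0.05 in all 6 named German windows, but the differences stayed about as large. They were 20.4, 18.01 and 15.6 percentage points in the 3 higher windows, against 18.7, 18.4 and 17.5 before, and -15.4, -12.8 and -12.8 in the 3 lower ones, against -18.1, -12.95 and -12.5. The tested level of a location was that of its summed reads, so deep samples weighed more in the p-values than in the means given. Thinning leaves fewer reads and also gives a position the same weight in every sample, Germany 6 included, and these were not told apart. It raised the counts of Australia (277 to 558) and Thailand (82 to 357) and lowered those of Germany (33 to 3), Finland, Iran and the USA. Over shared positions thinned to 10 reads the difference was 8.29 on chromosome 3 (adjusted p = 0.790) and -14.7 on chromosome 5 (adjusted p = 0.656). Leaving out Germany 6, the deepest sample and the German one with a signal on chromosome W, moved the count to 129 over all positions, to 5 over concordant pairs and to 6 over shared positions.

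Samples from Iran and the USA were called in the fewest windows. The USA samples were called in 24 windows, higher in 15 and lower in 9, over concordant pairs in 4, all of them lower, and over shared positions in 8, higher in 2 and lower in 6. No USA window was higher over concordant pairs by the quasi-binomial test, and 18 had an unadjusted p under 0.05 with that difference. On chromosome 2 at 32714501 to 32715000 the USA samples lay at 54.8% ± 4.70 (SD, n = 6) and the other locations at a mean of 68.5% (adjusted p = 0.00210). The difference there was -14.9 percentage points over concordant pairs (adjusted p = 0.00591), -16.9 over 9 shared positions (adjusted p = 2.5e-05) and -15.6 with these thinned to 10 reads each (adjusted p = 0.0153). On chromosome 6 at 33841501 to 33842000 they lay at 71.5% ± 4.48 (n = 5) against 86.1% (adjusted p = 0.00269), with -14.5 percentage points over 3 shared positions (adjusted p = 0.0132). Thinning each position to 10 reads left a difference of -14.8, against -14.6 before, with an adjusted p of 0.0740, and over the thinned shared positions it was -16.7 (adjusted p = 0.172). Of the 6 named USA windows 3 could be tested over shared positions, and these 2 were called again. The remaining one, on chromosome 3 at 10488501, had -13.0 percentage points (adjusted p = 0.0589). The 3 higher windows could not be tested there, and the one on chromosome 24 at 4536501 was lost over concordant pairs (adjusted p = 0.150). Iranian samples were called in 13 windows, higher in 7 and lower in 6, over concordant pairs in 3, all of them higher, and over shared positions in 3, higher in 1 and lower in 2. No Iranian window was lower over concordant pairs by the quasi-binomial test, and 20 had an unadjusted p under 0.05 with that difference. On chromosome 11 at 943501 to 944000 Iran lay at 51.4% ± 6.25 (n = 6) against 63.3% (adjusted p = 0.0249), with -12.7 percentage points over 3 shared positions (adjusted p = 0.0375). Thinning each position to 10 reads ended the call, with a difference of -8.59 (adjusted p = 0.479), and over the thinned shared positions it was -8.09 (adjusted p = 0.316). Of the 6 named Iranian windows 2 could be tested over shared positions and only this one was called again. The other, on chromosome 11 at 11011001, had a difference of 1.63 percentage points there (adjusted p = 0.311). Over concordant pairs 2 could be tested and 0 were called again.

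These counts moved with single samples. Over all positions the Iranian count ranged from 1 (without Iran 5) to 45 (without Iran 6) and the USA count from 8 (without USA 3) to 40 (without USA 6). Over concordant pairs the Iranian count ranged from 0 (without Iran 1, Iran 2 or Iran 5) to 11 (without Iran 6, 6 higher and 5 lower) and the USA count from 1 (without USA 3) to 20 (without USA 6, 4 higher and 16 lower). Over shared positions the Iranian count ranged from 0 (without Iran 1 or Iran 5) to 9 (without Germany 6) and the USA count from 3 (without USA 4) to 18 (without USA 6). Where the count was 0 by the quasi-binomial test, between 38 and 60 windows had an unadjusted p under 0.05 with the minimum difference.

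**Figure D4:**
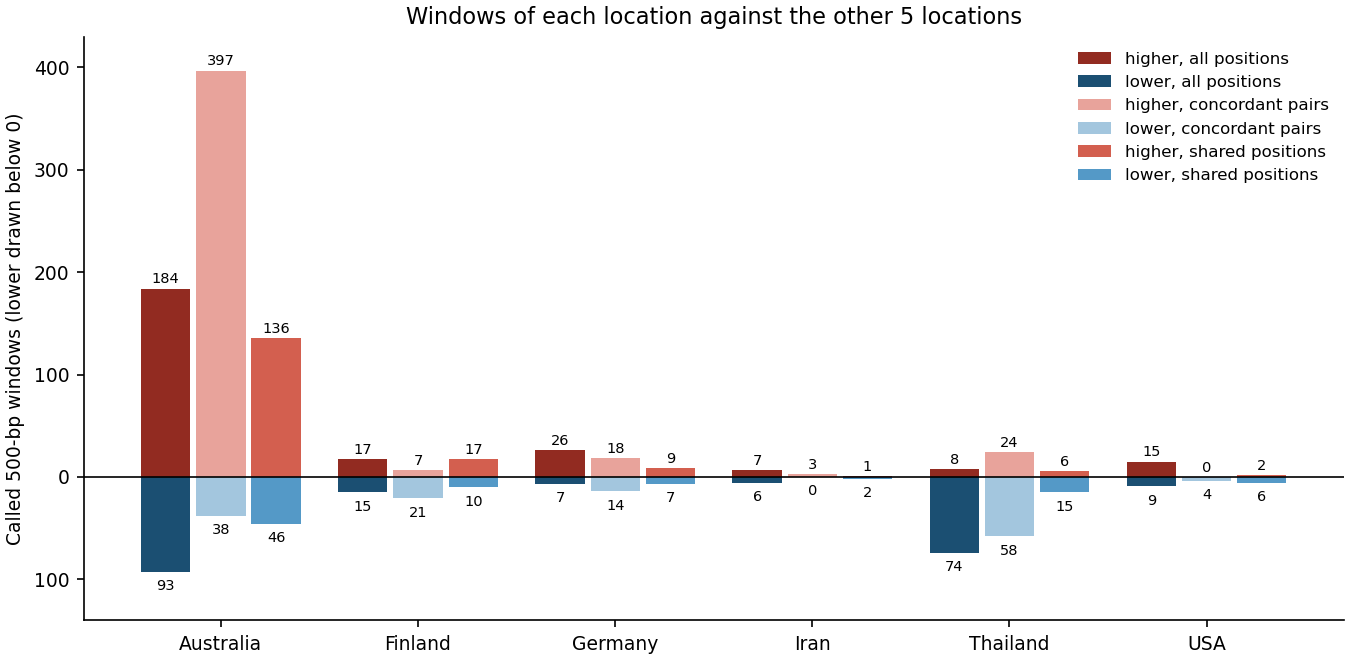
Number of 500-bp windows in which each location was called against the mean of the other 5, with higher windows drawn above 0 and lower windows below 0, over all positions (darkest bars), shared positions (medium bars) and concordant CpG pairs (lightest bars). Australia had 184 higher and 93 lower windows over all positions, 136 and 46 over shared positions and 397 and 38 over concordant pairs.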

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

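Among the tests in this part, those over concordant CpG pairs and over shared positions, the test of the Thai windows over shared positions and the choice of samples by their chromosome Z coverage were chosen only after the result was seen. The remaining tests of explanations were stated before their own values were computed, but on patterns already noticed in these data. The counts of called windows were compared with those of 99 random splits of the 36 samples into groups of the same sizes. In each comparison over all positions the real split was the 1 of 100 with a count as large. That is the smallest share these splits can give, so it argues against chance without excluding it. The comparisons were not adjusted for their number. Each random split mixed the samples of all locations, so it does not test 1 location with the others kept as they are. The real count and the highest of the other splits were 1580 and 33 for all locations, 277 and 17 for Australia, 32 and 6 for Finland, 33 and 12 for Germany, 13 and 5 for Iran, 82 and 7 for Thailand, and 24 and 12 for the USA. With single samples left out the Iranian count ranged from 1 to 45 and the USA count from 8 to 40. The lowest of these lie under the highest other split, so the argument against chance is weaker for these 2 locations. Over shared positions the real count and the highest of the other splits were 785 and 25, 182 and 3, 27 and 2, 16 and 6, 3 and 3, 21 and 3, and 8 and 7 in the same order. There the real split alone reached the count for all locations together and for Australia, Finland, Germany, Thailand and the USA. For Iran another split matched the count and for the USA one nearly did, so chance stays open for both. The Iranian count of 3 was reached by 2 of 100 splits, so another split gave as many, and it fell to 0 without Iran 1 or Iran 5. Over concordant pairs chance cannot be excluded for Iran, where 6 of 100 splits reached the real count of 3 and the highest other gave 10, or for the USA, where 5 of 100 reached the real count of 4 and the highest other gave 56. Over the shared positions of concordant pairs the values were 981 and 45, 294 and 45, 14 and 3, 7 and 5, 2 and 16, 19 and 7, and 5 and 64 in the same order; the Iranian count was reached by 6 of 100 splits, so that chance cannot be excluded, the USA count by 4 of 100 and the others by the real split alone. Some splits gave several times the real count, which points to a structure of the samples; which samples formed them was not examined, and location itself is not excluded as that structure.

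The called windows lay among many CpG pairs whose positions were read at opposite levels, and samples of different depth were measured at different positions of a window. In 90.9% of discordant pairs high at the second position the next discordant pair within 300 bp was high at the first position, at a median distance of 64 bp, and of those high at the first position 14.3% were followed by one high at the first position too; this is consistent with cytosines filled in at fragment ends during library preparation. Of the 1580 windows called between locations 1072 could be tested over concordant pairs, and 68.9% of these were called again. This argues against discordant pairs as the whole source in those 1072 windows. By location 142 of 185 Australian, 30 of 36 Thai, 15 of 18 German, 7 of 15 Finnish, 3 of 17 USA and 1 of 7 Iranian windows were called again. Discordant pairs stay open as a source of the Finnish, USA and Iranian calls. They also stay open for the windows with too few concordant pairs for a test, as 277 Australian, 82 Thai and 33 German windows had been called. Without genotype-like positions 99.4% of 1578 windows were called again, but such positions numbered 1975 of 4662607, so few windows could change. This shows only that the calls did not rest on positions of that definition, and genotype stays open as a source. Different positions in different samples stay open as a source: over shared positions 35.8% of 1049 windows were called again, 22.9% of 175 Australian, 9.43% of 53 Thai and 7 of 19 Finnish, 7 of 13 German, 2 of 8 Iranian and 3 of 14 USA windows. The median share of the difference left was 63.8% for the 1049 windows called between locations, and 52.3, 19.6, 65.9, 94.5, 97.2 and 83.2% in the order of these locations, so the median German, Iranian and USA window kept most of its difference. With these positions thinned to 10 reads each, which leaves fewer reads, 66 of 1049 (6.29%) were called again. By location these were 32 of 175 Australian, 0 of 53 Thai, 0 of 19 Finnish, 0 of 13 German, 0 of 8 Iranian and 1 of 14 USA windows. The median share left was then 53.4% between locations, and 38.4, 24.2, 38.1, 102.6, 80.3 and 69.5% in the same order. The loss of most Thai calls, with most of their difference, is consistent with this explanation. A difference between flocks in genotype beyond such positions, in keeping or in handling was not tested.

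The higher level of weakly methylated positions in Australia was weighed against incomplete bisulfite conversion. Where the other 30 samples averaged under 1% (239981 positions), Australia was higher by 0.836 percentage points (SE 0.0741), where they averaged 1 to 2% (48379 positions) by 0.946 (SE 0.0903), at 2 to 5% (26226 positions) by 1.37 (SE 0.149) and at 5 to 10% (15497 positions) by 2.12 (SE 0.304). The rise argues against a failure that acted alike on all cytosines as the whole of the difference, but most positions lie in the lowest 2 ranges, where the difference was nearly flat, and such a failure stays open as a part of it. At weakly methylated mitochondrial positions Australia was higher by 0.424 percentage points (SE 0.0984, permutation p = 0.0258), against 0.943 (SE 0.0842) at nuclear positions. These values leave incomplete conversion open, as 39 mitochondrial positions are few and Thai samples averaged 1.71% ± 0.435 there (SD, n = 6) beside 1.53% ± 0.210 in Australian ones (n = 6). A biological difference between the Australian samples and the others was not tested apart from location.

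Germany 6, USA 1 and USA 5 had a signal on chromosome W, with coverage relative to the numbered chromosomes of 0.0990, 0.356 and 0.355, against 0.00904 to 0.04996 in the other 33 samples, and chromosome Z coverage of 0.541 to 0.559 against 0.905 to 1.22; chickens with a W chromosome are female. In USA 1 and USA 5, the samples with a chromosome W ratio over 0.2, all values lay apart from the other samples in 5.06% of 1541 chromosome Z windows, against 0.339% of windows on numbered chromosomes (Fisher's exact p = 4.7e-55), and in all 3 samples in 0.520% of 1539 chromosome Z windows, against 0 of 36609 on numbered chromosomes (p = 6.9e-12, neighbouring windows not being independent). Over shared positions the values were 1.24% of 1376 chromosome Z windows against 0.499% for USA 1 and USA 5 (Fisher's exact p = 0.00164) and 0.0727% against 0.00318% for all 3 samples (p = 0.0821). Thinning these samples on the numbered chromosomes to their chromosome Z coverage gave 0.00819%, but it left their positions as they were, so fewer reads, through the positions they leave, are not excluded. The sex of the birds and different positions cannot be told apart for these windows, because most of the excess was lost over shared positions, and reads from chromosome W placed on chromosome Z remain open.

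In 6 of 88 groups of samples 1 sample lay far from the others, where chance gives about 1 in 20 groups. A Thai sample had a mean level of 16.5%, with the other Thai samples at 16.9 to 17.1%, and a Thai sample had 19.8% on the remaining numbered chromosomes, with the others at 20.4 to 20.7%. On chromosome 5 at 17525501 a Thai sample lay at 37.5%, with the others at 28.8 to 30.9%. On chromosome 3 at 10491001 an Iranian sample lay at 24.9%, with the others at 37.3 to 42.7%, and on chromosome 27 at 615501 an Iranian sample lay at 24.5%, with the others at 7.96 to 11.5%. On chromosome 20 at 5482001 a USA sample lay at 85.3%, with the other 4 measured at 65.6 to 71.2%. Mitochondrial positions, which the comparisons did not use, held 15 discordant pairs among 64, with a median level of 93.9% at the high position.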

How the results depend on the processing

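The values over concordant CpG pairs and over shared positions, alone, together, with the replicate block or with thinned reads, were chosen only after the result was seen; the other alternatives were planned. The order of Australia over Iran in mean level, over all numbered chromosomes and in the 3 chromosome classes, and the permutation test between locations kept their direction and their side of the threshold in each alternative except the weighting of each read equally. With it the difference was -0.313 percentage points over all of them, -0.277 on chromosomes 1 to 5, -0.202 on chromosomes 6 to 12 and -0.126 on the remaining numbered chromosomes; the cause was not tested. Averaged over each sample's own positions the differences were 0.0494, 0.209, 0.198 and 0.127 in this order, and with a minimum of 20 reads 0.540, 0.505, 0.586 and 0.561, beside 0.922, 0.776, 0.896 and 1.15 as reported. The share of variation taken up by location was 25.5 to 39.3% and the number of samples nearest to their own location 19 to 26 over the alternatives.

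Counts of called windows moved by more than 1.5 times as follows, and the cause was not tested unless stated. With a minimum of 5 reads, 2504 windows were called between locations, 455 for Australia, 67 for Finland (49 higher, 18 lower), 77 for Germany, 30 for Iran (6 higher, 24 lower), 127 for Thailand and 48 for the USA (13 higher, 35 lower). With a minimum of 20 reads, which tests fewer windows, they were 769, 121 for Australia, 20 for Germany, 3 for Iran, 20 for Thailand and 9 for the USA. Among windows measured in all 36 samples they were 726, 127 for Australia (104 higher, 23 lower), 15 for Finland (5 higher, 10 lower), 7 for Germany, 3 for Iran, 30 for Thailand and 10 for the USA. With no minimum difference they were 16606, 10139, 11046, 1626, 244, 3101 and 819 in the order of all locations, Australia, Finland, Germany, Iran, Thailand and the USA, and with at least 20 percentage points 74, 9, 3, 1, 0, 1 and 1. The Iranian 0 came from the quasi-binomial test, and 0 windows with that difference had an unadjusted p under 0.05 or were called by limma.

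Reads thinned to 10 per position gave 558 for Australia (492 higher, 66 lower), 18 for Finland (4 higher, 14 lower), 3 for Germany, 2 for Iran, 357 for Thailand and 3 for the USA. Windows of 1000 bp gave 50 for Finland (16 higher, 34 lower) and 7 for Iran (1 higher, 6 lower). Shared positions gave 785 between locations, 182 for Australia (136 higher, 46 lower), 16 for Germany (9 higher, 7 lower), 3 for Iran (1 higher, 2 lower), 21 for Thailand (6 higher, 15 lower) and 8 for the USA (2 higher, 6 lower), and 27 for Finland (17 higher, 10 lower). Shared positions of concordant pairs gave 981 between locations, 14 for Finland, 7 for Germany, 2 for Iran, 19 for Thailand (5 higher, 14 lower) and 5 for the USA, with 294 for Australia (268 higher, 26 lower); all 5 of the USA were lower, and 13 higher ones had an unadjusted p under 0.05 in the quasi-binomial test. Shared positions thinned to 10 reads, which leave fewer reads, gave 159 between locations, 193 for Australia (163 higher, 30 lower), 1 for the USA and 0 each for Finland, Germany, Iran and Thailand by the quasi-binomial test, where 82, 95, 86 and 75 windows had an unadjusted p under 0.05 with that difference. Concordant pairs gave 435 for Australia, 3 for Iran and 4 for the USA, and with the replicate block 436, 2 and 5. With log10 mean coverage as a covariate 90 windows were called for Germany and 22 for Iran, and with the replicate block and log10 mean coverage 88 for Germany and 12 for the USA. The chromosome W coverage ratio as a covariate gave 13 for the USA. With limma on logit levels 14 were called for Finland, 137 for Germany, 32 for Thailand and 9 for the USA.

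The replicate numbers did not pair the samples: deviations of the 90 same-numbered pairs correlated at -0.432 to 0.288, and 7 of 36 samples correlated best with their own number. The replicate block gave 1520 windows between locations, 278 for Australia, 32 for Finland, 32 for Germany, 6 for Iran, 84 for Thailand and 8 for the USA, and ended no call of mean level or similarity. With it the adjusted p of the German window on chromosome 3 at 10491001 was 0.0940 (0.0855 with log10 mean coverage too) and of that on chromosome 17 at 9106501 0.0743.

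With each sample left out in turn, the counts ranged from 1479 to 1876 between locations, 220 to 349 for Australia, 26 to 37 for Finland, 28 to 129 for Germany, 1 to 45 for Iran, 56 to 119 for Thailand and 8 to 40 for the USA. The German count was 129 without Germany 6. The Iranian count was 25 without Germany 6, and 4, 7, 7, 5, 1 and 45 without Iran 1 to Iran 6 in turn. The USA count was 12 without USA 1, 14 without USA 2, 8 without USA 3, 13 without USA 5 and 40 without USA 6. Over concordant pairs the ranges were 1216 to 1736, 387 to 606, 18 to 40, 5 to 36, 0 to 11, 66 to 133 and 1 to 20 in the order of all locations, Australia, Finland, Germany, Iran, Thailand and the USA, over shared positions 691 to 929, 157 to 258, 23 to 31, 6 to 20, 0 to 9, 16 to 29 and 3 to 18, and over the shared positions of concordant pairs 771 to 1198, 251 to 445, 14 to 21, 0 to 13, 0 to 7, 14 to 25 and 1 to 8. Over concordant pairs single samples moved the count to 18 for Finland (without Finland 6), 5 for Germany (Germany 6), 0 (Iran 1, Iran 2 and Iran 5), 1 (Iran 4) and 11 (Iran 6) for Iran, 133 for Thailand (Thailand 5), and 1 (USA 3), 7 (Thailand 2), 12 (Germany 3), 15 (USA 4) and 20 (USA 6) for the USA. Over shared positions they moved it to 6 for Germany (Germany 6), 0 (Iran 1 and Iran 5), 1 (Iran 3), 5 (Finland 2 and Thailand 5), 6 (Thailand 1), 8 (Iran 6) and 9 (Germany 6) for Iran, and 3 (USA 4), 5 (USA 3) and 18 (USA 6) for the USA. Over the shared positions of concordant pairs they moved it to 445 for Australia (Australia 5), 0 (Germany 6), 4 (USA 5), 11 (Germany 1) and 13 (Germany 5) for Germany, 0 (Iran 1 and Iran 5), 4 (Iran 2) and 7 (Iran 6) for Iran, and 1 (USA 2), 2 (USA 1, USA 3 and USA 5) and 8 (USA 4) for the USA. Each of these counts of 0 came from the quasi-binomial test, with 38 to 65 windows at an unadjusted p under 0.05. The difference in mean level ranged from 0.822 to 1.05 percentage points over all numbered chromosomes and from 0.672 to 0.865, 0.788 to 1.02 and 1.05 to 1.33 in the 3 chromosome classes, the share taken up by location from 28.5 to 31.1%, and samples nearest to their own location from 22 to 25.

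Of 2016 values of named windows with a sample left out, 1950 kept their direction and an adjusted p under 0.05 and 66 their direction alone. Of 693 values under the other alternatives 567 kept both, 109 their direction alone and 17 reversed. The direction held with an adjusted p over 0.05 in 30 of 56 tests after thinning, which leaves fewer reads, 10 of 56 with limma, 4 of 56 with log10 mean coverage, 8 of 56 with the replicate block, 6 of 21 over concordant pairs, 9 of 32 over shared positions, 20 of 32 over shared positions thinned to 10 reads and 5 of 11 over the shared positions of concordant pairs. The reversed differences, in percentage points, over shared positions were -4.44 on chromosome 14 at 692001, -1.58 on chromosome 24 at 1481501, -1.38 on chromosome 5 at 36389001 and -4.48 on chromosome 8 at 28851501 between locations, -0.517 for Australia on chromosome 3 at 65049501 and -0.920 for Thailand on chromosome 1 at 49630501; the samples of a location are no longer measured at different positions there. Over the shared positions of concordant pairs they were -0.0265 on chromosome 8 at 28851501 and -0.592 for Finland on chromosome 27 at 615501. Over shared positions thinned to 10 reads they were -1.78 on chromosome 3 at 65049501, -4.17 on chromosome 14 at 692001, -7.22 on chromosome 5 at 36389001 and -1.94 on chromosome 8 at 28851501 between locations, -0.444 for Australia on chromosome 3 at 65049501, -0.238 for Finland on chromosome 27 at 615501, and -0.156 on chromosome 13 at 1784001, -2.60 on chromosome 1 at 49630501 and 1.87 on chromosome 5 at 36389001 for Thailand; the cause was not tested beyond this. Promoter alternatives were not run. Median coverage of 4 to 35 reads per position limits what single positions show, and differences under 10 percentage points were left uncalled by design.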

Other observations

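The values in this part come from shared positions or, where stated, from concordant CpG pairs, sets chosen only after the result was seen, and the windows and stretches named here were chosen after their values were seen. Australia was higher on chromosome 27 at 1776001 to 1776500, with 52.7% ± 6.33 (SD, n = 6) against a mean of 30.9% over 6 shared positions (adjusted p = 0.000636), and with these thinned to 10 reads each the difference was 23.1 percentage points (adjusted p = 0.00258). On chromosome 10 at 557501 to 558000 Australia lay at 42.8% ± 7.93 (n = 6) against 21.7% over 3 shared positions (adjusted p = 0.00104). Australia was lower on chromosome 11 at 2039001 to 2039500, with 31.5% ± 2.73 (n = 6) against 47.5% over 18 shared positions (adjusted p = 0.00280). On chromosome 12 at 15317001 to 15317500 it lay at 3.18% ± 2.28 (n = 5) against 19.7% over 3 shared positions (adjusted p = 0.0263). Thinning to 10 reads kept the last 3 of these calls too, with adjusted p-values of 0.00104, 0.0296 and 0.00536. Of the 4 windows with the largest Australian difference in each direction over shared positions, thinning kept the call in all 4 higher and in 2 of the 4 lower ones. The largest lower difference, on chromosome 11 at 713501 to 714000 with 14.7% ± 6.12 (n = 6) against 33.2% over 3 shared positions (adjusted p = 3.5e-07), was -6.44 percentage points after thinning (adjusted p = 0.0641). On chromosome 10 at 15848001 to 15848500, with 45.6% ± 9.01 (n = 5) against 61.6% (adjusted p = 0.000307), it was -14.3 (adjusted p = 0.0596).

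Some called windows lay close together. The stretch with the most called windows over concordant pairs ran on chromosome 1 from 78651001 to 78664000, with 10 of 15 tested windows called, and 6 of 12 over the shared positions of these pairs. Over the latter the mean level was 41.4% ± 6.44 in Thailand (SD, n = 6), 41.2% ± 7.37 in Germany, 40.1% ± 2.56 in Finland, 36.1% ± 3.89 in Iran, 35.5% ± 3.62 in Australia and 31.8% ± 8.27 in the USA. On chromosome 2 from 305501 to 324500, 7 of 20 tested windows were called, and 5 of 19 over the shared positions, with 52.1% ± 2.41 in Australia (n = 6) and means of 41.3 to 44.8% in the other locations. No test was run on these stretches.

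Samples of a location could lie far apart within a window. In 26 of 785 windows called over shared positions (3.31%) the samples of a location spanned at least 40 percentage points, against 71 of 30740 other windows (0.231%). Of the called windows 92.0% had a mean level of 20 to 80%, while 58.7% of those tested lay under 20%, where such a span is harder to reach. No comparison at like levels was made, so level can account for a part of this contrast.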
